A study of Mus musculus with 21 samples.

How the data were processed

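Mouse endothelial cells were measured by bulk RNA-seq (3 brain, 3 lung and 3 liver libraries), ATAC-seq (4 brain, 4 lung and 3 liver libraries) and single-cell RNA-seq (1 library of brain cells). Per the labels' protocols, mice were perfused, tissues were digested with collagenase, dispase and DNase, myelin was removed from brain alone, and live cells positive for CD31 and negative for PDGFRβ and CD45 were sorted. Samples were grouped by the tissue and assay that the labels give. A pair of ATAC columns named for lung without a usable number, called a and b here, entered as lung libraries with no number of their own. The RNA table held 9 further columns of per-sample values that belong to no sample or group, and these were not used.

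The RNA values were raw counts per gene symbol made by the authors, per the file headers. The ATAC values were deposited counts of reads per peak over 60119 peaks; per the file headers the peaks form 1 merged set of the tissues with a library called lung 3 left out. The single-cell values were deposited UMI counts for 32285 genes and 9405 barcodes; filters on cells before deposit were not given in the sources used here. Per the submitters' processing notes the tools were TopHat, Bowtie2, SAMtools 1.10.2, HTSeq 0.6.1, Picard, MACS2, bedtools and Cell Ranger 1.2.0, with builds mm9 and mm10, and no tool or build was tied to an assay. Chromosome names in the ATAC table occur in mm9 and not in mm10, so peak positions are given in mm9, counted from 1. The annotation at hand was of another build, so peaks carry no gene names and the planned comparison of RNA with ATAC per gene was not run. Of 24176 symbols in the RNA table, 22805 matched a symbol of the mouse gene table. Strand use in counting was not given in the sources used here, so overlapping or antisense genes, Fendrr among them, and near-identical genes such as hemoglobins, MHC genes and Hspa1a with Hspa1b are uncertain.

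Depth per library is given with the results. A count of 0 over a group's libraries was set to a floor of 3 counts, and folds against such a group are lower bounds for counting error only.

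The tests ran on the deposited counts with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 13216 genes and 58293 peaks, TMM scaled the libraries, and all libraries of an assay entered 1 quasi-likelihood fit with a mean per tissue (robust). The biological coefficient of variation was 0.766 for RNA and 0.275 for ATAC. A gene or peak was called at a Benjamini-Hochberg adjusted p under 0.05 over all features tested and an absolute log2 fold change of at least 1. A feature was enriched in a tissue when called higher against both others. Levels are CPM as mean ± SD over libraries.

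The 30 gene lists, the rule for the genes to be named and the tests between tissues were fixed before the data were examined; the closing section says which of its tests were chosen later. The lists covered pan-endothelial genes, junctions, barrier solute carriers, ABC efflux, receptors and transcytosis, Wnt/β-catenin, brain endothelial transcription factors, liver sinusoidal and lung endothelial genes, Hox genes, leukocyte adhesion and antigen presentation, TGF-β and BMP, Notch, basement membrane, lipid metabolism, Alzheimer's disease risk orthologs, dissociation and stress, and cell cycle. They also covered markers of mural cells, astrocytes, microglia and macrophages, neurons, oligodendrocytes, hepatocytes, lung epithelium, fibroblasts, leukocytes, erythroid cells, lymphatic endothelium and Kupffer cells. The lists share some genes, such as Cdh5, Lef1, Clu and Lyve1. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with an estimated correlation, and with fry, adjusted over the lists of a comparison; no Kupffer cell gene passed the count filter. Genes named in the text were, per comparison and tissue signature, the 6 with the largest fold in each direction among called genes with a mean log2 CPM of at least 5 and no overlap between libraries, up to 4 called members of each list with the largest fold, every called Alzheimer's disease ortholog, and Pecam1, Cdh5, Cldn5, Slc2a1, Mfsd2a, Plvap, Stab2 and Car4; the text gives part of these, and 1 result is not reported here. For ATAC they were the 6 peaks with the largest fold in each direction with a mean log2 CPM of at least 3.

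The tests were tried on simulated data drawn from the real means and library sizes with 200 changed features. Recovery counted an adjusted p under 0.05 alone, without the minimum fold. Far fewer features changed than were called in the data, which makes the adjusted threshold stricter, so the shares recovered need not hold for the data. Between brain and lung, 2% of 2-fold and 10% of 4-fold changes among 13216 genes were recovered with 1 false call, and 24% and 71% among 58293 peaks with 3 false calls. Between brain and liver, 1% and 9% of gene changes were recovered, and 11% and 61% of peak changes. Of 30 simulated lists of 20 genes, camera called the 1 changed list, raised 4-fold in brain, and no other. Simulated genes were drawn independently, so this does not test false calls for lists of correlated genes.

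Single cells were analysed with scanpy 1.11.5. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept (8645 cells, 760 removed), scaled to 10000 UMIs, log-transformed, and clustered on 2000 variable genes, 30 principal components and 15 neighbours with Leiden at resolution 0.5. The plan did not say how neighbours are found; a first look used an approximate search and the values given use an exact one, chosen after that look. Clusters took a name when at least 3 markers fixed beforehand were among their 10 leading genes by fold, a number chosen after the first clusters were seen. The 3 clusters below it held 35.9%, 20.1% and 3.13% of cells and stayed unnamed. Scrublet called 4 doublets among 8645 cells, too few to have worked, so no doublets were removed, and the high UMI counts of erythroid-like cells (median 12280) leave doublets among them possible. Levels of list genes were compared between clusters drawn again without 152 list genes, as summed UMIs per 10000 with exact Poisson intervals; for the test of bulk signatures in fenestrated-like cells a further clustering left out the genes of both signatures; shares have exact Clopper-Pearson intervals.

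For the counts of calls and the named genes and peaks, the alternatives were DESeq2 size factors, library size alone, the Wald test of DESeq2 1.42.0, no count filter, the replicate number as a term, each library left out and pairs of tissues fitted alone; no minimum fold was tried for the counts alone. Gene lists were tested again with the list tests named above and with library size alone, and cell classes with other cell filters, resolutions and gene numbers. Alternatives without the abundant transcripts Rn45s, Malat1 and Lars2, without lung library 2 and liver library 2 of RNA together (the shallowest and the one with the lowest scaling factor), without lung libraries a and b of ATAC (the shallowest), with other Leiden seeds, with the approximate search and, for the genes tested in fenestrated-like cells, with UMIs counted in the other cells alone were added after the data were seen.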

Results

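Endothelial cells sorted from brain, lung and liver of C57BL/6J mice aged 2 to 4 months were profiled in 3 ways. Bulk RNA sequencing covered 3 libraries per tissue, and ATAC-seq, which marks open chromatin, covered 4 brain, 4 lung and 3 liver libraries. A single library held the single-cell transcriptomes of brain endothelial cells. The RNA libraries held 15907235, 17938723 and 21792786 counts in brain, 11308897, 2992101 and 6925167 in lung, and 18485600, 25690571 and 23367904 in liver. The ATAC libraries held 17956240, 6700965, 5003580 and 6995574 counts in peaks in brain. The lung ATAC libraries held 5857763, 6046832, 1335711 and 1244653, and those of liver 2162227, 2175575 and 1856763. The ribosomal transcript Rn45s took 12.2% to 28.8% of the RNA counts of a library and the nuclear transcript Malat1 1.44% to 7.74%; both were singled out after their shares were seen. The labels call the RNA libraries biological replicates and say nothing of animals or of the ATAC libraries, so the p-values measure the spread between these libraries, which may be technical.

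RNA libraries resembled those of their own tissue. Correlations of log2 CPM across genes, which are not independent replicates, reached 0.902 between RNA libraries of the same tissue, lay between 0.608 and 0.712 across tissues, and were higher within than across tissues for every pair. For ATAC peaks they were 0.935 to 0.962 within brain, 0.778 to 0.946 within lung, 0.841 to 0.86 within liver and 0.673 to 0.801 across tissues, so that the lowest pair within lung lay below the highest pair across tissues. The first and second principal components held 35.7% and 28.2% of the RNA variance and 41.5% and 19.5% of the ATAC variance.

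Brain endothelium forms the blood-brain barrier, and the comparison with lung asked which genes set it apart from capillaries that exchange gas. Brain cells carried far more transcript of nutrient carriers. Slc2a1, the glucose carrier of barrier endothelium, had a mean of 3330 ± 672 CPM in brain and 23.9 ± 11.8 CPM in lung (SD, n = 3). Slc7a5, which carries large neutral amino acids, had 1179 ± 286 and 11.8 ± 13.9 CPM. The organic anion carrier Slco1a4 had 4355 ± 348 CPM in brain and 0 counts in the 3 lung libraries, at least 33200-fold higher. Mfsd2a, a lipid carrier that restrains vesicle transport across the barrier, had 152.6 ± 34.0 CPM in brain and 0 counts in lung, at least 1160-fold higher. These lower bounds were set against a floor of 3 counts over the group's libraries, here and throughout, and cover counting error only. Lung cells carried more of Tspan7, a membrane tetraspanin (829 CPM in lung, 0.263 in brain), of the fatty acid receptor Cd36 (969 and 0.648 CPM) and of the water channel Aqp1 (1211 and 4.91 CPM).

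The edgeR quasi-likelihood test called 667 genes higher and 958 lower in brain than in lung among 13216 tested. The libraries of both tissues did not overlap for 1581 of these 1625 genes (97.3%), against 34.1% of all tested genes and a share of 10% given by chance. Here and in the comparisons below, the calls were made on these same libraries, so such shares follow in part from the call and are no separate support. Spock2, a secreted proteoglycan, rose most among called genes without overlap and with a mean log2 CPM of at least 5 over all libraries. That cut leaves out genes near absent from the other tissues, such as Slco1a4, whose lower bound was larger. The log2 fold change of Spock2 was 9.38 (SE 0.29, edgeR quasi-likelihood, BH-adjusted p = 2.34e-10). That of Slc2a1 was 7.11 (SE 0.71, edgeR adjusted p = 8.38e-05), that of fibronectin, Fn1, 5.81 (SE 0.42, edgeR adjusted p = 1.13e-06), and that of Tspan7 −11.58 (SE 0.35, edgeR adjusted p = 2.34e-10). The number of genes called higher in brain was 444 without lung library 2 and 432 without lung library 3, and the DESeq2 Wald test called 1446 lower. In simulated counts of 13216 genes, the test recovered 10% of 4-fold and 2% of 2-fold changes between brain and lung, so a gene without a call may still differ.

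Fixed gene lists placed these changes in known functions; counts in brackets were adjusted over the list alone and are given where they differed. Between brain and lung, 18 of 21 barrier solute carriers were higher in brain (camera, BH-adjusted p = 2.76e-20). So were 9 of 10 transcription factors of brain endothelium (adjusted p = 1.87e-10), among them Foxq1, at 183 CPM in brain and 0 counts in lung. Of 20 genes of Wnt/β-catenin signalling, which builds the barrier, 11 were higher (adjusted p = 8.34e-07) [11 higher, 1 lower]; its nuclear effector Lef1 had 548.7 ± 34.6 CPM in brain and 6.70 ± 3.00 in lung. Higher in brain were also 8 of 15 basement membrane genes, with 1 lower (adjusted p = 0.000967). Of 9 ABC efflux transporters, 5 were higher [5 higher, 1 lower], such as the drug pump Abcb1a, at 1337 ± 101 and 72.1 ± 4.94 CPM. The call for the efflux list, at an adjusted p of 0.00126, was lost with an estimated correlation between genes (adjusted p = 0.165). Lower in brain were 15 of 22 lung endothelial genes [18] (adjusted p = 1.95e-11) and 7 of 11 Hox genes [10] (adjusted p = 2.62e-09). Of 15 genes of leukocyte adhesion and antigen presentation, 10 were lower and 2 higher (adjusted p = 0.000589) [3 higher, 11 lower]. Hoxa5 and Hoxb4, which mark position along the body axis, had 0 counts in brain and 29.5 and 27.4 CPM in lung, at least 561-fold and 522-fold higher. The MHC class II chaperone Cd74 had 706 ± 510 CPM in lung and 0.357 in brain, and the class II gene H2-Aa 231 and 0.347. By library, lung had 394.39, 1295.14 and 428.91 CPM of Cd74, and leukocyte markers were higher in lung as well (2 of 8 genes lower in brain, adjusted p = 2.84e-06; Cd79a at 17.3 CPM in lung). Of 21 liver sinusoidal genes, 7 were lower in brain than in lung and 1 higher [1 higher, 8 lower], and 2 of 5 lymphatic genes were lower [3]. Their adjusted p-values of 0.0122 and 0.0117 became 0.165 and 0.082 with an estimated correlation. For the lymphatic list the estimate was −0.156, below the preset 0.01. Estimates for lung endothelial (0.00507), cell cycle (−0.0175), leukocyte adhesion (−0.0234) and transcytosis genes (0.00726) were below it as well. For these lists, calls lost here or below under that setting do not come from a higher correlation.

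Several endothelial lists were not called as a whole by camera between brain and lung. Of 16 pan-endothelial genes, 3 were higher and 3 lower (camera adjusted p = 0.915): the VEGF receptor Flt1 had 2960 CPM in brain and 608 in lung, and the adhesion gene Cdh5 1047 and 5307. Of 15 junction genes, 5 were higher and 1 lower (adjusted p = 0.0541). Cldn5, the main claudin of the barrier, differed by less than the test could call (388 ± 36.4 and 505 ± 147 CPM, log2 fold change −0.38, SE 0.26, edgeR adjusted p = 0.402). Not called either were the lists of receptors and transcytosis (4 higher and 4 lower of 18, adjusted p = 0.708) [4 and 5] and Notch signalling (2 and 1 of 12, adjusted p = 0.921) [2 and 2]. The same held for TGF-β and BMP signalling (4 and 3 of 17, adjusted p = 0.921) [6 and 4] and lipid metabolism (1 and 6 of 17, adjusted p = 0.326) [2 and 6]. Within these lists, the apolipoprotein E receptor Lrp8 rose to 541 CPM in brain from 0.258 in lung, and Plvap, the diaphragm protein of fenestrated vessels, fell from 453 ± 215 to 19.1 ± 5.34 CPM. Of 10 cell cycle genes edgeR called 0 in either direction (camera adjusted p = 0.175), with 4 lower at an unadjusted p under 0.05 and 1 lower by DESeq2. The fry test, which does not set a list against other genes, called junction genes higher in brain than in lung (adjusted p = 0.00147) and lipid metabolism (adjusted p = 0.00178) and cell cycle genes (adjusted p = 0.0182) lower.

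**Figure D1:**
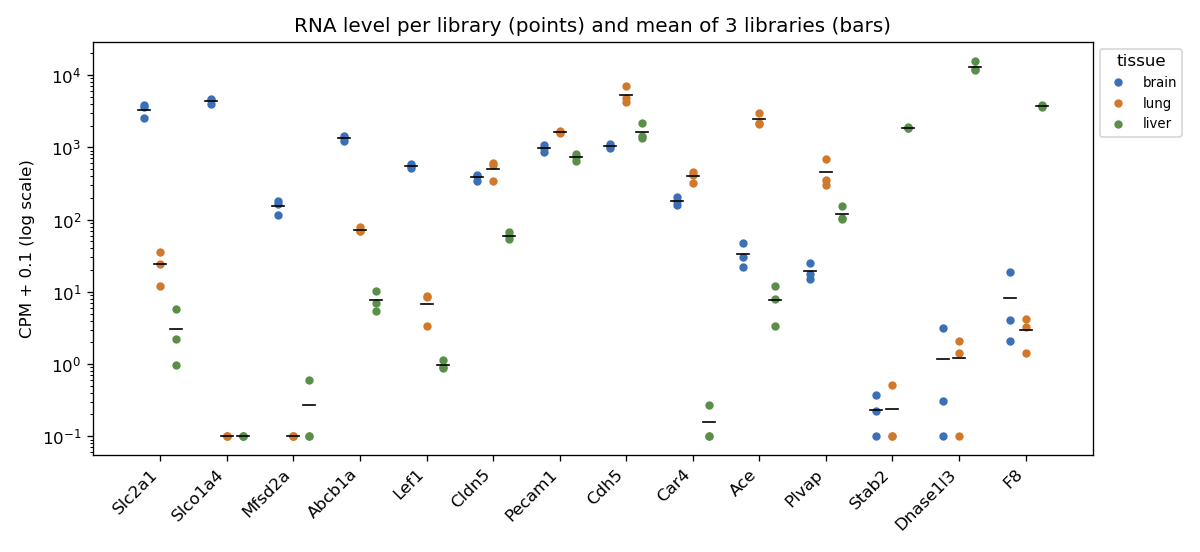
RNA level (CPM + 0.1, log axis) of 14 genes in each library of brain, lung and liver endothelial cells; points are libraries and bars the means of 3. Carriers such as Slco1a4 stood out in brain, Ace in lung, and Stab2, Dnase1l3 and F8 in liver.

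The comparison of brain with liver set a closed barrier against the sinusoid, whose wall is open and clears proteins from blood. Barrier carriers again stood out in brain: Slc2a1 had 3330 CPM in brain and 2.90 ± 2.51 in liver, and Slco1a4 had 0 counts in liver (at least 88500-fold higher in brain). The junction protein Ocln had 202 CPM in brain and 0 counts in liver (at least 4110-fold higher). Liver cells carried the scavenger receptor Stab2 at 1876 ± 46.8 CPM against 0.128 in brain and the DNase Dnase1l3 at 13090 ± 2170 against 1.08. Coagulation factor F8 stood at 3728 ± 75 against 8.20, and the transcription factor Maf at 1809 ± 481 against 4.56. Gata4, a regulator of sinusoidal identity, had 755 ± 388 CPM in liver and 0 counts in brain, at least 14400-fold higher.

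The test called 985 genes higher and 1152 lower in brain than in liver, and for 2087 of these 2137 (97.7%) the libraries did not overlap, against 33% of all tested genes and 10% by chance. The log2 fold change was 14.13 for Spock2 (SE 0.35, edgeR adjusted p = 2.11e-11), 10.17 for Slc2a1 (SE 0.81, edgeR adjusted p = 1.02e-05) and 9.28 for Lef1 (SE 0.46, edgeR adjusted p = 3.05e-08). It was −13.79 for Stab2 (SE 0.75, edgeR adjusted p = 6.54e-08) and −8.63 for Maf (SE 0.43, edgeR adjusted p = 3.05e-08). Scaling by library size alone moved the median of all genes by 0.158 between brain and liver and by 0.212 between lung and liver on the log2 scale.

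All 21 tested liver sinusoidal genes were lower in brain than in liver (camera adjusted p = 1.14e-26), as were 9 of 11 Hox genes [10] (adjusted p = 4.82e-12) and 3 of 5 lymphatic genes [4] (adjusted p = 0.000265). Higher in brain were 18 of 21 barrier solute carriers [19] (adjusted p = 2.89e-18) and all 10 brain endothelial transcription factors (adjusted p = 1.72e-12), among them Foxf2, at 160 CPM in brain and 0 counts in liver. The calls for 4 further lists higher in brain were lost with an estimated correlation. These were the Wnt list (11 higher and 3 lower of 20, adjusted p = 1.04e-05, then 0.0679) and the junction list (6 higher of 15, adjusted p = 0.00223, then 0.0877). The others were the Notch list (3 higher of 12, adjusted p = 0.0142, then 0.111) and the efflux list (4 higher and 1 lower of 9, adjusted p = 0.0267, then 0.266). Cldn5 was higher in brain (388 against 59.4 ± 6.53 CPM, log2 fold change 2.71, SE 0.28, edgeR adjusted p = 1.34e-05), and the Notch target Hey1 had 114 and 5.01 CPM. Of 22 lung endothelial genes, 7 were higher in brain than in liver and 5 lower [8 and 5], with an adjusted p of 0.0485 that was 0.139 with an estimated correlation and 0.0717 with scaling by library size alone. Of 10 cell cycle genes, 2 were lower in brain (adjusted p = 0.0308, and 0.116 with an estimated correlation). Camera called no other endothelial list, at adjusted p-values from 0.106 for basement membrane (6 higher and 1 lower of 15) to 0.964 for pan-endothelial genes (4 and 4 of 16). Of these, fry called basement membrane (adjusted p = 2.12e-05) and receptors and transcytosis (adjusted p = 0.00103) higher in brain than in liver, and lipid metabolism lower (adjusted p = 0.0015).

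Lung and liver were compared with each other to separate what is particular to brain from what differs between any pair of vascular beds. Lung cells carried Ace, which makes angiotensin II, at 2433 ± 517 CPM against 7.64 ± 4.30 in liver and the sodium channel gene Scn7a at 1918 ± 474 against 0.404. The long noncoding RNA Fendrr stood at 2462 ± 791 against 0 counts, at least 50000-fold higher. Car4, a carbonic anhydrase of alveolar capillaries, had 395 ± 63.9 CPM in lung and 181 ± 22.4 in brain, with 3 counts over the liver libraries. Liver cells carried Stab2, Dnase1l3 and F8, which had 0.137, 1.1 and 2.86 CPM in lung, and Oit3, a secreted protein of sinusoids, at 1819 ± 80.3 CPM against 0.279.

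The test called 1063 genes higher and 928 lower in lung than in liver, and for 1934 of these 1991 (97.1%) the libraries did not overlap, against 34.9% of all tested genes and 10% by chance. The log2 fold change was 8.32 for Ace (SE 0.53, edgeR adjusted p = 3.9e-07), −13.10 for Stab2 (SE 0.75, edgeR adjusted p = 2.31e-07) and −12.23 for Oit3 (SE 0.49, edgeR adjusted p = 5.2e-08). The total was 1312 without lung library 3, and the number called lower in lung was 598 without lung library 2 and 539 without lung library 3. Without lung library 2 and liver library 2, chosen after the data were seen, RNA lung vs liver calls numbered 1239, with 518 lower. With scaling by library size alone 1185 genes were higher and 645 lower, so that the share called higher was 64.8% instead of 53.4%.

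In the lists, 19 of 22 lung endothelial genes were higher in lung than in liver (camera adjusted p = 5.85e-16), and 18 of 21 liver sinusoidal genes were lower [19] (adjusted p = 1.45e-22). With an estimated correlation 3 calls were lost. These were Notch signalling (4 higher of 12, adjusted p = 0.00594, then 0.0838) [6] and leukocyte adhesion and antigen presentation (7 higher and 2 lower of 15, adjusted p = 0.0135, then 0.0838) [7 and 3]. Leukocyte markers were also higher in lung than in liver (3 of 8, adjusted p = 1.73e-05, and 0.021 with an estimated correlation). The third lost call was receptors and transcytosis (7 higher and 2 lower of 18, adjusted p = 0.0166, then 0.0933) [8 and 2]. The caveola protein Cav1 had 1600 CPM in lung and 73.1 in liver, and Plvap 453 and 120. Camera called no other endothelial list, at adjusted p-values from 0.135 to 0.867. Among them were barrier solute carriers (8 higher and 5 lower of 21, adjusted p = 0.577) [9 and 6], brain endothelial transcription factors (3 higher of 10, adjusted p = 0.135) [4] and the Wnt list (7 higher and 3 lower of 20, adjusted p = 0.345) [9 and 3]. Of 11 Hox genes edgeR called 0 (adjusted p = 0.135), with 2 lower at an unadjusted p under 0.05 and 1 lower by DESeq2. By fry the lists of junctions (adjusted p = 0.000223), brain endothelial transcription factors (0.000805), barrier solute carriers (0.021) and the Wnt genes (0.0277) were higher in lung than in liver. Basement membrane (0.000456), lymphatic (0.00295) and Hox genes (0.00735) were lower. Over the 3 comparisons camera called 38 list results, 22 with an estimated correlation, and fry called 59. Among list results without a call, those of neurons, fibroblasts, leukocytes, oligodendrocytes, pan-endothelial, Notch, TGF-β and BMP, basement membrane, cell cycle, lipid and Alzheimer's disease genes had a median, mean and test that differed in sign in at least 1 comparison.

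**Figure D2:**
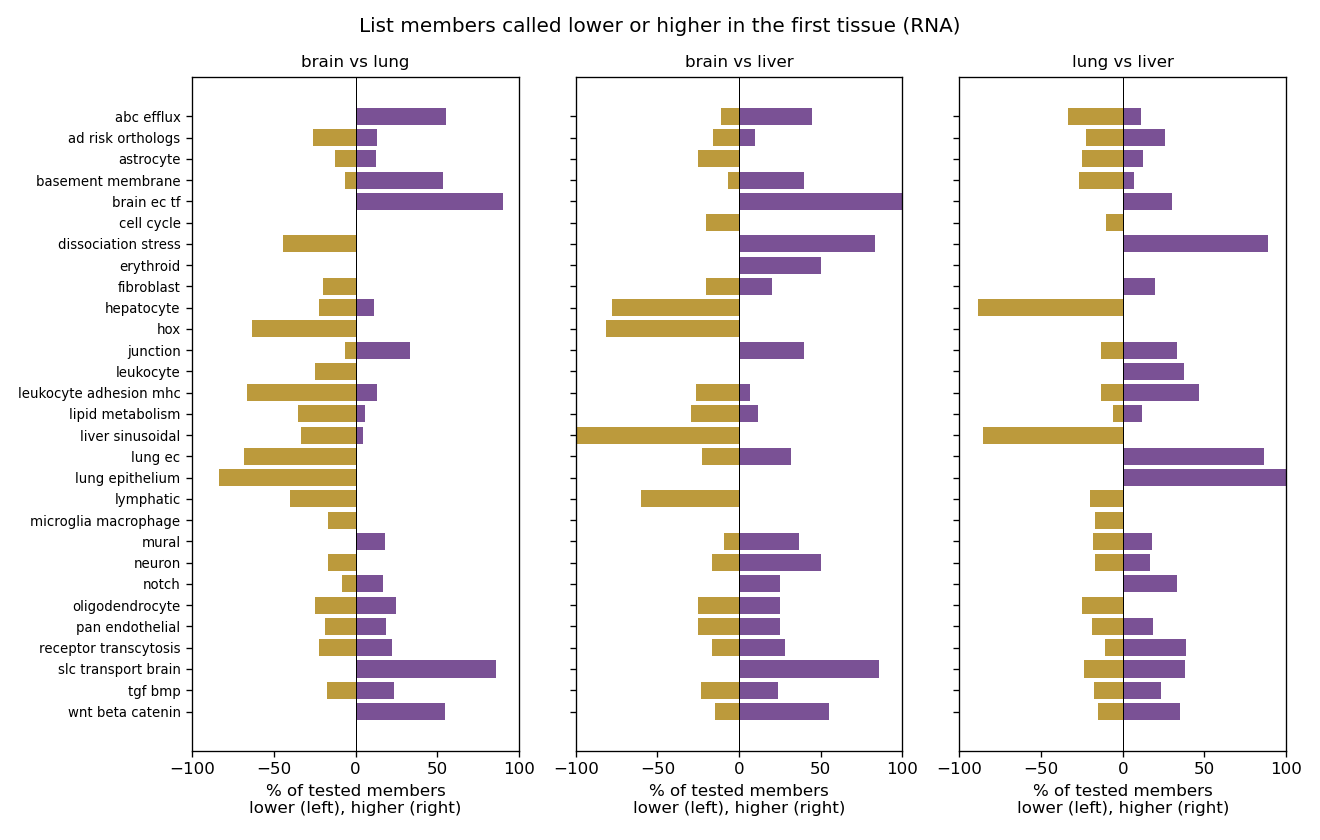
Genes of each fixed list called higher or lower in the 3 RNA comparisons, as a percentage of the tested members of the list. Barrier solute carriers were higher in brain against both other tissues (18 and 18 of 21), and liver sinusoidal genes were lower in brain than in liver (21 of 21).

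Genes called higher in a tissue against both others made up a signature of each bed: 319 genes in brain, 409 in lung and 490 in liver. Independent lists of the same sizes would share 49.7, 77.1 and 80.9 genes. In 5 simulations without differences edgeR called 0 such genes, and part of the excess may still come from the libraries that both contrasts share. The brain signature held Spock2, Slc2a1, Fn1, Slc6a6, which carries taurine (4303 CPM against 198 in lung and 166 in liver), and Bsg, the chaperone of monocarboxylate carriers (2835 ± 427 against 70.6 and 76.1). The lung signature held Ace, Fendrr, the endothelin receptor Ednrb (700 CPM against 16.3 in brain and 41.9 in liver) and the transcription factor Casz1 (539 against 10.6 and 12.3). The liver signature held F8, Maf and Ehd3, an endocytic regulator (6357 ± 2250 CPM against 31.4 in brain and 44.2 in lung). The lung signature fell to 242 genes without lung library 2, the shallowest RNA library.

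Markers of other cell types were measured beside these groups. Hepatocyte genes were higher in liver than in brain (7 of 9, camera adjusted p = 2.64e-08) [1 higher and 7 lower in brain] and than in lung (8 of 9, adjusted p = 9.06e-12) [9]. Alb, the most abundant of those named, had 309 ± 97.7 CPM in liver and 0 counts elsewhere, at least 5880-fold above brain. Lung epithelial genes were higher in lung than in brain (5 of 6, adjusted p = 4.12e-08) and in liver (6 of 6, adjusted p = 1.93e-08). The club cell gene Scgb1a1 had 840 ± 771 CPM in lung and 0 counts in the other tissues. Leukocyte genes were higher in lung than in brain (2 of 8, adjusted p = 2.84e-06) [6] and than in liver (3 of 8, adjusted p = 1.73e-05) [6], such as the B cell gene Cd79a at 17.3 ± 4.47 CPM. In brain, the choroid plexus transcript Ttr had 433 ± 449 CPM and Mal, a myelin gene, 433 ± 141 CPM, while Rgs5, a pericyte gene, had 36.3 ± 44.5. Mural genes were higher in brain than in lung (2 of 11, adjusted p = 0.0425) and than in liver (4 higher and 1 lower, adjusted p = 0.0271). Erythroid genes were higher in brain than in liver (2 of 4, adjusted p = 0.00833) [4]. These 3 calls were lost with an estimated correlation, at adjusted p-values of 0.392, 0.322 and 0.253.

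Camera called none of the remaining marker lists in any comparison. Between brain and lung, fibroblast genes (1 lower of 5, camera adjusted p = 0.0889) [2], microglia and macrophage genes (1 lower of 6, adjusted p = 0.326) [2] and oligodendrocyte genes (1 higher and 1 lower of 4, adjusted p = 0.504) were not called as lists. Nor were astrocyte genes (1 and 1 of 8, adjusted p = 0.921) and neuron genes (1 lower of 6, adjusted p = 0.922) [1 and 1]. Between brain and liver their adjusted p-values lay between 0.22 and 0.992, and between lung and liver between 0.205 and 0.769. By fry, microglia and macrophage genes (adjusted p = 0.0058) and fibroblast genes (0.0171) were lower in brain than in lung and oligodendrocyte genes higher (0.0471). Against liver, fry called neuron genes higher in brain (0.0015) and microglia and macrophage genes lower (0.0168), and neuron (0.0031) and fibroblast genes (0.0148) higher in lung. In the bulk libraries the microglial gene C1qb had 1.43 CPM in brain and the neuronal genes Snap25 and Syt1 5.02 and 2.99. The microglial gene Cx3cr1, singled out after its values were seen, did not pass the count filter, with 169, 8 and 422 counts in the brain libraries and 0 in all others. Hepatocyte genes were not called as a list between brain and lung (adjusted p = 0.916), nor were lung epithelial and leukocyte genes between brain and liver (adjusted p = 0.609 and 0.992). None of the 6 markers of Kupffer cells, the macrophages of liver, had enough counts for the test; Cd5l had 39, 2 and 63 counts in the liver libraries.

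The series sets brain endothelium beside Alzheimer's disease, and the mouse orthologs of risk genes were followed as a list. The list as a whole was not called between brain and lung (4 higher and 8 lower of 31, camera adjusted p = 0.0889) [4 and 12]. Nor was it called between brain and liver (3 and 5, adjusted p = 0.445) or between lung and liver (8 and 7, adjusted p = 0.622). The fry test called it lower in brain than in lung (adjusted p = 0.00141) and higher in lung than in liver (adjusted p = 0.00944). Cd2ap, an adaptor of the endocytic and actin machinery, was higher in brain, at 652 ± 148 CPM against 87.5 ± 23.6 in lung (log2 fold change 2.89, SE 0.28, edgeR adjusted p = 1.62e-05). In liver it had 211 ± 2.85 CPM (log2 fold change 1.63, SE 0.27, edgeR adjusted p = 0.000841). Apoe, which carries lipids, had 93.2 ± 31.3 CPM in brain, 19.8 ± 16.9 in lung and 536 ± 129 in liver, where hepatocyte transcripts were present. Adam10, a secretase of the amyloid precursor, had 188 CPM in brain and 38.4 in lung. Lower in brain than in lung were the chaperone Clu (65.4 against 271 CPM), the guanine nucleotide exchange factor Rin3 (91.1 against 460) and Abi3, an actin regulator (18.4 against 175).

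Genes that respond to tissue dissociation and early signals differed between the beds. Of 18 such genes, 15 were higher in brain than in liver [16] (camera adjusted p = 1.91e-08), and 16 higher in lung than in liver [18] (adjusted p = 4.1e-12). In brain 8 were lower than in lung [9] (adjusted p = 0.0017), a call lost with an estimated correlation (adjusted p = 0.181). The transcription factor Egr1 had 339 ± 56.1 CPM in brain, 5068 ± 1140 in lung and 119 ± 25.3 in liver, Atf3 90.9, 604 and 23.2, and the nuclear receptor Nr4a1 175, 236 and 14.4.

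Open chromatin was compared between the same beds to find the regions that may carry their regulation. Peaks are given by position in build mm9, which the chromosome names of the table point to, and without gene names, since the annotation in hand was of another build. A peak on chromosome 13, 26792402 to 26793848, had 265.7 ± 36.7 CPM in brain (SD, n = 4), 4.87 ± 1.80 in lung (n = 4) and 28.6 ± 12.9 in liver (n = 3). A peak on chromosome X, 55509043 to 55510143, had 85.9, 2.06 and 7.09 CPM in the same order. Lung was marked by a peak on chromosome 8, 123399902 to 123401067, at 123 ± 37.6 CPM against 3.13 in brain and 6.79 in liver, and by one on chromosome 5, 119914473 to 119915117, at 50.2 against 1.78 and 5.06. Liver was marked by a peak on chromosome 3, 144306151 to 144306851, at 60.5 CPM against 5.12 in brain and 4.63 in lung. A peak on chromosome 4, 31353534 to 31354184, was open in brain and liver, at 28.4 and 29.2 CPM, and near closed in lung, at 1.47.

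Of 58293 peaks tested, edgeR called 8756 higher and 9194 lower in brain than in lung, 7611 higher and 11028 lower in brain than in liver, and 3208 higher and 4824 lower in lung than in liver. Libraries did not overlap for 14581 of the 17950 brain and lung calls (81.2%, chance 2.86%), 16694 of the 18639 brain and liver calls (89.6%, chance 5.71%) and 7052 of the 8032 lung and liver calls (87.8%, chance 5.71%). Among all tested peaks these shares were 31.9%, 41.5% and 25.1%. Between brain and lung the log2 fold change was 5.87 for the peak on chromosome 13 (SE 0.34, edgeR adjusted p = 4.24e-28) and −5.46 for the lung peak on chromosome 8 (SE 0.36, edgeR adjusted p = 8.4e-18). The peak on chromosome 11, 110861076 to 110861943, had a log2 fold change of 4.28 in brain against liver (SE 0.36, edgeR adjusted p = 9.48e-17). The peak on chromosome 14, 101288929 to 101289449, had one of −4.77 (SE 0.34, edgeR adjusted p = 5.81e-20). Between lung and liver, the peak on chromosome 15, 74739874 to 74740770, had a log2 fold change of 3.53 (SE 0.32, edgeR adjusted p = 5.77e-15) and the peak on chromosome 4 of −3.98 (SE 0.39, edgeR adjusted p = 2.32e-13).

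Peaks called higher in a tissue against both others numbered 5471 in brain, 1857 in lung and 2939 in liver, where independent lists of the same sizes would share 1140, 506 and 913. With the brain libraries split between the contrasts, the brain number was 4882 to 5164, against 999 to 1260 for independent lists. Median widths were 576 bp for brain peaks, 448 bp for lung peaks and 342 bp for liver peaks, and 418 bp for all peaks tested. Depth also differed, at 5003580 to 17956240 counts per library in brain, 1244653 to 6046832 in lung and 1856763 to 2175575 in liver. Whether these numbers and widths follow depth was not tested. With scaling by library size alone, the share called higher fell from 40.8% to 24.8% in brain against liver (4548 higher and 13757 lower) and from 39.9% to 23.8% in lung against liver (1797 and 5742). The number of ATAC brain-enriched peaks was 3632 and that of ATAC lung-enriched peaks 1222. That scaling moved the median of all peaks by −0.109, −0.318 and −0.207 on the log2 scale in the 3 comparisons. In simulated counts, 71% of 4-fold changes between brain and lung and 61% of those between brain and liver were recovered.

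**Figure D3:**
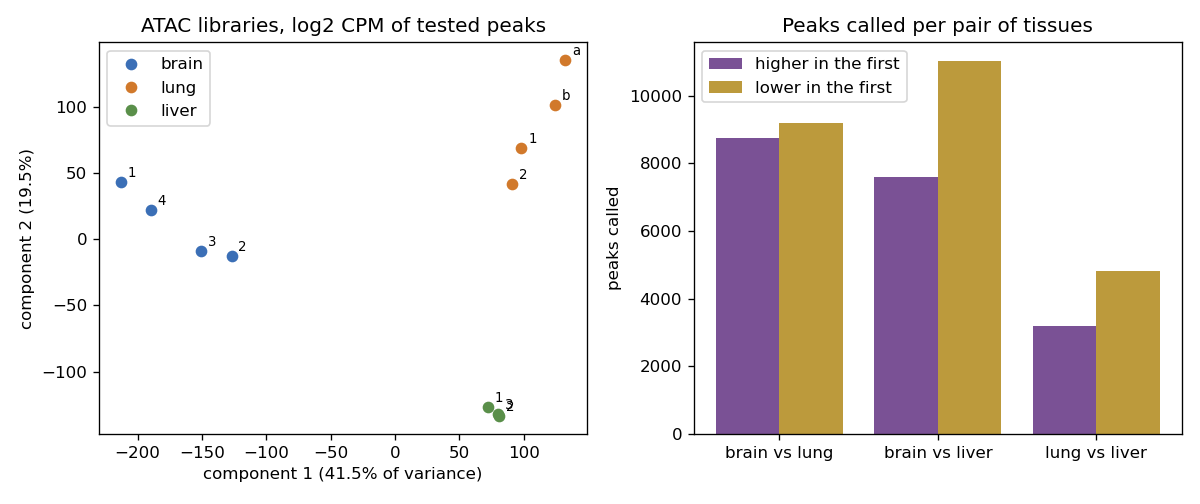
Left, ATAC libraries on the first and second principal components of log2 CPM (points are libraries, numbers and letters their names); right, peaks called per pair of tissues. Brain separated from lung and liver along the first component (41.5% of variance), and 11028 peaks were lower in brain than in liver.

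The single-cell library asked which endothelial classes make up the brain preparation, which had been sorted as CD31 positive, PDGFRβ and CD45 negative. It held 9405 barcodes with 45602016 UMIs, of which 8645 cells passed the filters, with a median of 4563 UMIs and 2110 genes. With 1 library there is no test, and intervals cover counting error only (95%, exact). Fenestrated-like cells, named from Plvap, Esm1 and Plpp3 and resembling the endothelium of the choroid plexus, made up 1.83% of cells (158 cells, 1.56% to 2.13%). Erythroid-like cells made up 0.775% (67 cells, 0.601% to 0.983%) and mural-like cells, named from Pdgfrb, Rgs5 and other markers, 0.37% (32 cells, 0.253% to 0.522%), shares that the sort gate can set. A cluster led by Ttr and Enpp2, with a median of 1219 UMIs, held 3.13% of cells and stayed unnamed. So did a cluster of 20.1% led by the stress genes Fosb, Fos, Hspa1a and Hspa1b and a cluster of 35.9% led by Ivns1abp. Arterial-like cells (19.2%, named from Mgp, Gkn3, Fbln5, Bmx and Vegfc) and venous-like cells (18.7%, named from Lcn2, Vcam1, Ackr1 and Icam1) depended on the clustering: over its alternatives their shares ran from 0% to 23.1% and from 0% to 24.5%.

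Barrier genes were compared between clusters drawn without the genes of the lists, which gave 157 fenestrated-like, 164 arterial-like and 32 mural-like cells and a largest cluster of 3171 cells called cluster 1. These clusters differed from the first ones (adjusted Rand index 0.298): arterial-like cells numbered 1658 before, and 65.6% of the 1973 redrawn venous-like cells lay in the first venous-like cluster. Slc2a1 had 35.1 UMIs per 10000 in cluster 1 and 28.9 in arterial-like cells. It had 3.46 (3.09 to 3.86) in fenestrated-like cells, close to the 2.77 (2.10 to 3.59) of mural-like cells, where free RNA and doublets with endothelial cells were not told apart. Slco1a4 stood at 44.9 in cluster 1, 3.82 in fenestrated-like and 3.64 in mural-like cells, Abcb1a at 17.1, 2.37 and 2.09, and Cldn5 at 43.6, 4.99 and 4.66. The Wnt effector Lef1 had 6.57 in cluster 1, 0.736 in fenestrated-like and 0.971 in mural-like cells. In fenestrated-like cells these 5 genes were thus near their levels in mural-like cells, while the efflux pump Abcg2 stood at 5.83 against 1.65. A UMI of Slc2a1 was seen in 38.9% of fenestrated-like and 34.4% of mural-like cells. The transferrin receptor Tfrc had 6.31 UMIs per 10000 in venous-like cells, 0.566 in arterial-like and 0.461 in fenestrated-like cells.

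Among the Alzheimer's disease orthologs, Clu had 9.19 UMIs per 10000 (8.62 to 9.79) in arterial-like cells, 1.56 in fenestrated-like cells and 0.082 in cluster 1. The angiotensin converting enzyme Ace had 1.96 in arterial-like cells and 0.0488 in cluster 3, a cluster led by Hspa1b and Hspa1a. Abi3 was highest in fenestrated-like cells, at 1.08 (0.874 to 1.31) against 0.0971 in cluster 1. Mef2c had 10.2 (9.51 to 10.8) in fenestrated-like and 7.19 (6.07 to 8.44) in mural-like cells against 2.40 in cluster 1. Cd2ap had 8.43 in cluster 1, 10.6 in arterial-like, 3.35 in fenestrated-like and 1.65 in mural-like cells. Of 149 list genes with a UMI, 111 differed at least 2-fold between a pair of clusters with intervals apart, and 101 of 146 did so after each cell was thinned to 2000 UMIs. Any pair without the mural-like and erythroid-like clusters counted, with no adjustment for the number of pairs. The share over all genes was not measured, so these counts do not set the list genes apart.

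**Figure D4:**
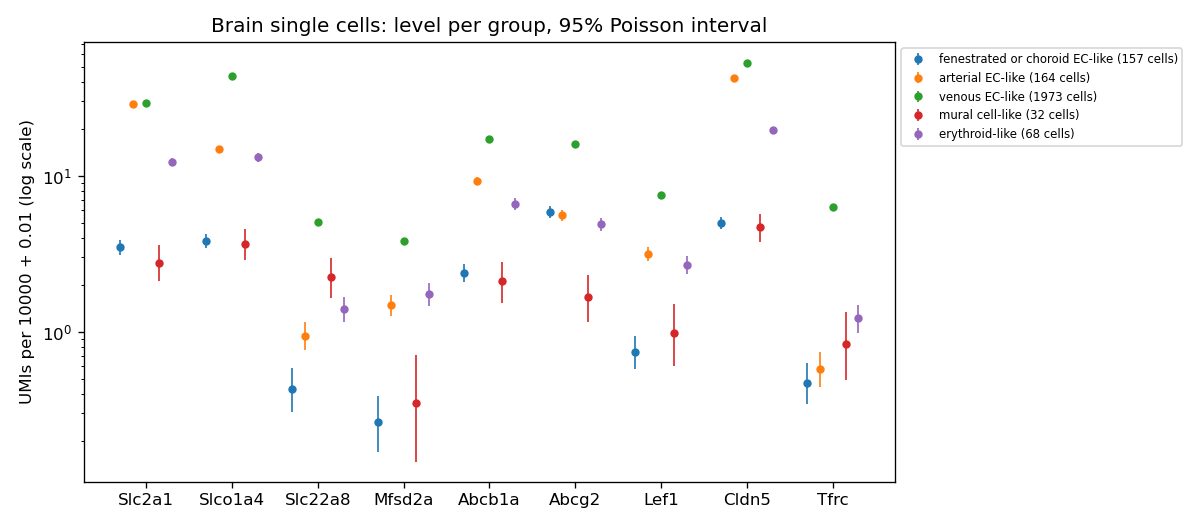
UMIs per 10000 (plus 0.01, log axis) of 9 genes in named clusters of brain cells drawn without the list genes; points are summed levels and bars 95% Poisson intervals, which cover counting error only. Slc2a1 stood at 3.46 in fenestrated-like and 2.77 in mural-like cells, and at 28.9 in arterial-like cells.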

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

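The test for samples far from the others was fixed beforehand; among the explanations weighed below, those on hepatocytes, on dissociation genes and on more female animals were chosen after the result was seen.

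A sample stood far from the others of its group in 7 of 70 groups tested, by the gap to its nearest neighbour over the range of the group. Chance marks about 1 in 20 groups, and groups of 3 were not tested. Brain ATAC library 1 held 17956240 counts in peaks against 5003580 to 6995574 in the other brain libraries (ratio 0.846); without it, 15370 peaks were called between brain and lung and 14965 between brain and liver. The other 6 were single peaks. In brain these were chromosome 11, 110861076 to 110861943 (ratio 0.896; brain library 3 at 84.3 CPM against 66.5 to 68.4), and chromosome 16, 87261697 to 87262221 (0.852; brain library 2 at 11.9 against 18.2 to 19.3). In lung they were chromosome 10, 21119882 to 21120563 (0.874; lung library a at 12 against 3.74 to 4.78) and chromosome 5, 100098853 to 100099396 (0.87; lung library 2 at 11.1 against 7.85 to 8.27). The last lung peaks were chromosome 8, 58814154 to 58814727 (0.913; lung library 1 at 16.3 against 23.1 to 23.8), and chromosome 15, 74739874 to 74740770 (0.855; lung library 1 at 143 against 78.9 to 88.2).

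Brain-enriched peaks were more frequent on chromosome X, where they made up 17.4% of peaks (198 of 1136) against 9.24% of autosomal peaks and at most 12% on any autosome. Scaling cannot be the whole cause, since the ratio of these shares was 1.89 and rose to 2.1 with scaling by library size alone. With more female animals behind the brain libraries, the share of counts in chromosome Y peaks would be lower in brain than in lung. Over 7 such peaks it was 1.57 times as high in brain as in lung (90.3 to 96 CPM in brain, 47.8 to 73.3 in lung, 75.9 to 89.6 in liver). This went against that explanation but cannot exclude it, since the opening of 7 peaks can also differ by tissue. In RNA, chromosome Y genes stood at 124 to 216 CPM in brain, 48.8 to 122 in lung and 61.2 to 146 in liver. Xist stood at 5.41, 8.36 and 0.78 CPM in the brain libraries, at most 1.41 in lung and at most 1.54 in liver. The chromosome Y genes argue against any RNA library from female animals alone. Shares of female animals that differ between tissues, and the sex behind the ATAC libraries, cannot be told apart from tissue. The median log2 fold change of X peaks lay above that of autosomal peaks by 0.42 for brain against lung, 0.75 for brain against liver and 0.26 for lung against liver. Tissue stays open as the biological explanation.

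Liver-enriched genes could come from hepatocyte RNA, since Alb had 309 CPM in the liver libraries (207 to 402), although the sort for CD31 selects against such cells. Of 490 liver-enriched genes, 132 (26.9%) had a higher liver mean than Alb and 358 were at or below it. Alb as the upper limit of hepatocyte RNA is an assumed profile that no table measures, and its libraries spread on both sides of the mean. Hepatocytes and endothelium therefore cannot be told apart for either group by this test.

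Dissociation and immediate-early genes were higher in brain and lung than in liver. Myelin removal was done for brain alone, so it cannot account for the 16 of 18 such genes higher in lung than in liver. That lung was higher was part of the pattern and known before this test. Whether myelin removal added to the excess in brain, where 15 of 18 were higher than in liver, was not tested. In the single cells of brain, 6 list members were among the 10 leading genes of a cluster that held 20.1% of cells, so expression was uneven between cells of 1 preparation. All tissues were digested, and a response to the digestion cannot be told apart from a state present in the animal.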

How the results depend on the processing

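Alternatives without lung library 2 and liver library 2, without lung libraries a and b, without Rn45s, Malat1 and Lars2, with other Leiden seeds with an approximate neighbour search and with UMIs counted in other cells alone were chosen after the data were seen; all others were planned.

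No called gene, peak or list among those named reversed under an alternative tried for it; some lists without a call changed direction between tests. Of 8580 values of named genes and peaks under alternatives, 8117 kept their call and 463 lost it. Counts of calls stayed within 1.5 times their value except as follows, and the cause was not tested. RNA lung vs liver fell from 1991 to 1239 and RNA liver-enriched from 490 to 323 without lung library 2 and liver library 2. Leaving out 1 library at a time gave 1312 to 1978 for RNA lung vs liver and 242 to 381 for RNA lung-enriched, which was 409. With scaling by library size alone ATAC brain-enriched fell from 5471 to 3632 and ATAC lung-enriched from 1857 to 1222. By direction, RNA brain vs lung higher fell from 667 to 444 and 432 without lung library 2 or 3, and RNA brain vs lung lower rose from 958 to 1446 with the DESeq2 Wald test. RNA lung vs liver lower fell from 928 to 598 and 539 without lung library 2 or 3, and to 518 without lung library 2 and liver library 2. With library size alone, ATAC brain vs liver higher fell from 7611 to 4548 and ATAC lung vs liver higher from 3208 to 1797. RNA gene lists called by camera numbered 38, with an estimated correlation 22, and by fry 59. Leaving out 1 library at a time, ATAC brain vs lung ran from 15370 to 18205, ATAC brain vs liver from 14965 to 19884, RNA brain vs lung from 1108 to 1957 and RNA brain vs liver from 1683 to 2131. The DESeq2 Wald test called 2392, 2837 and 2744 genes in the 3 comparisons, with 1590, 2093 and 1938 shared.

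In scRNA cell classes, arterial EC-like and venous EC-like cells (19.2% and 18.7%) moved under every clustering alternative, and the cause was not tested. Their shares were 1.51% and 6.98% with at least 1000 genes per cell, 0% and 2.32% with at least 200 genes, 23.1% and 20.2% with at most 5% mitochondrial UMIs, 16.8% and 0% at resolution 0.3, 6.06% and 15.8% at resolution 1.0, and 21.4% and 24.5% with 1000 variable genes. With the approximate search they were 4.44% and 1.32%. With Leiden seeds 1 to 5 they were 17.3% and 16%, 21.8% and 1.33%, 12.1% and 1.27%, 15.5% and 16.9%, and 21.9% and 13.4%. In the same scRNA cell classes, erythroid-like cells rose from 0.775% to 1.08% with at least 200 genes.

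No clear pairing by replicate number was seen, which neither shows nor excludes shared animals or days. Deviations of same-numbered libraries correlated between −0.0033 and 0.078 for RNA and between −0.17 and 0.11 for ATAC. Not every library correlated best with its own number. With the number as a term 1440, 1870 and 1660 genes were called, and ATAC brain vs lung gave 14747, ATAC brain vs liver 16644 and ATAC lung vs liver 6435 peaks. The planned comparison of RNA with ATAC and the alternatives for normalized values were not run, the first for want of an annotation in mm9 and the others because the tables hold counts. Changes near the limit of depth and spread are missed: between brain and lung, 10% of simulated 4-fold changes among 13216 genes and 71% among 58293 peaks were recovered, at coefficients of variation of 0.766 and 0.275. The shallowest libraries held 2992101 (RNA, lung library 2) and 1244653 counts (ATAC, lung library b).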

Other observations

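The tests on fenestrated-like cells and the splits of the libraries were planned before their results were seen; the filter on other cells alone was added after.

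Fenestrated-like cells of brain were compared with the bulk signatures, on the hypothesis that they carry less of the brain program and more of the program that other beds share. For this, cells were clustered again without the genes of both sets tested. The cluster was then named over all genes from fixed markers. Among these was Plvap, itself higher in lung and liver than in brain and so a member tested. Over 294 of the 319 brain-enriched genes with at least 100 UMIs, the median log2 ratio of 140 fenestrated-like cells to the 8406 cells outside the fenestrated-like, mural-like and erythroid-like clusters was −1.45; not all of these were shown to be endothelial. It lay below all 10000 matched random lists (percentile 0; 95% of lists from −0.12 to −0.01), and 21 of the genes were higher. Over 224 of 437 genes higher in lung and liver than in brain the median was 1.12 (percentile 100; 95% of lists from −0.13 to 0.01), and 201 were higher. Counting UMIs in all cells lets a gene pass through the fenestrated-like cells themselves, so UMIs were also counted in the other cells alone. The medians were then −1.45 over 292 genes (percentile 0) and 1.02 over 209 genes (percentile 100; 186 higher). Both results went the way of the hypothesis, in 1 library. Random lists do not keep the correlation between genes, and the naming used Plvap, so the percentiles are no independent support. In that library Slc2a1, Slco1a4, Abcb1a, Cldn5 and Lef1 in fenestrated-like cells were near their levels in mural-like cells. Free RNA and doublets were not told apart.

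Library labels were exchanged between tissues to ask whether chance can be excluded, counting the real grouping among the splits. In each result only 1 split, the real one, gave as many calls. For the RNA pairs there were 10 splits each, too few to exclude chance, with 1625, 2137 and 1991 calls and at most 0, 0 and 1 in another split. For ATAC, the real grouping gave the most calls of 35 splits for brain and lung (17950 calls, at most 1 in another split). It did so for brain and liver (18639 and 10360) and for lung and liver (8032 and 3843). In the splits with 10360 and 3843 calls the 3 liver libraries stayed in 1 group, with brain library 2 and lung library b. The same held for the RNA signatures over 100 splits (319, 409 and 490 genes, at most 171, 169 and 173 in another) and for the ATAC signatures over 30 splits (5471, 1857 and 2939 peaks, at most 0, 0 and 924). For the ATAC pairs and the signatures, these ranks make a chance result unlikely. They were not adjusted over the results, and the signatures rest on the same libraries as the pairs.

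Chromosome Y genes stood at 48.8 to 216 CPM in every bulk RNA library. Xist stood at 5.41, 8.36 and 0.78 CPM in the brain libraries, 0.578 to 1.41 in lung and 0 to 1.54 in liver.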
